A study of Homo sapiens with 2 samples.

How the data were processed

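RNA of MCF7 cells, an established human breast cancer line, was compared on 2 two-colour Agilent whole-genome expression arrays. Per the labels, each array carried cRNA from cells transfected with a negative control siRNA in Cy3 (green) and from cells transfected with an siRNA against CRY2 in Cy5 (red). The design text gives 2 independent cell populations per treatment, and each array was taken as 1 replicate of a single group, CRY2 siRNA over control siRNA. The dyes were not swapped on either array, so a dye effect of a probe cannot be separated from the treatment by the design. Both arrays lay on 1 slide and had 1 scan date, so neither slide nor scan date divided the comparison. Batches of transfection, RNA preparation or labelling were not assessed.

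The deposited intensity values are mean pixel intensities of each spot and median intensities of its local background, as scanned with Agilent Feature Extraction 9.5.3.1, per the file headers. The deposited processed intensities were background-subtracted with spatial detrending and dye-normalized with linear and lowess steps by that software, per the file headers. The deposited log ratio is the log10 of the red over the green processed signal, and the deposited p-value of each spot comes from the software's error model within 1 array, per the file headers. The deposited flags for outlier, saturated and well-above-background spots were used as given. A deposited series table of 33578 rows holds log10 ratios as well. Set against the scanner values, it equalled the log10 ratio within 0.0001 for 99.8% of the 26760 transcripts with 1 spot, and for 92.3% of the 6818 with several spots it lay within 0.001 of their error-weighted mean. Its direction is therefore red over green, and the median of each column was 0. How the submitters combined spots is not given in the sources used here.

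Each array held 45015 spots, of which 1639 were controls. Signals were background-corrected in limma 3.58.1 (R 4.3.3) by normexp with an offset of 50 on the mean signals and the median local background, with control spots in the fit. Loess normalization followed within each array with control spots at weight 0. Spots flagged as outliers (151 and 93 on the arrays) were left out, and spots of a probe were averaged. A probe was tested if it was well above background in at least 1 channel on both arrays. A gene whose control signal was not well above background was thus measured only if its CRY2 siRNA signal was, and the reverse. Of 41000 gene probes, 31 had no value on both arrays after flags, 17430 were below the filter and 23539 were tested. Log2 ratios were fitted against an intercept with lmFit and eBayes and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. All changes are log2 ratios of CRY2 siRNA over control siRNA, averaged over both arrays. The fit had 1 residual degree of freedom per probe and 2.98 prior degrees of freedom borrowed across probes.

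The local background was far below the signal of the negative control spots: its median was 34.0 in green on both arrays against negative-control signals of 642 and 640, and 45.5 and 46.0 in red against 852 and 944. Local background subtraction leaves this pedestal in place, so ratios of dim probes are compressed toward 0 in the main values. The means of the 10 spike-in transcripts spanned 0.64 on the log2 scale in the main values and 3.01 in the deposited log ratios. Several of these spikes were not well above background and their mixed amounts are not given in the sources used here, so they do not show which values lie nearer to the true ratios.

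Probes were named through the RefSeq gene table supplied for this work (GRCh38.p14, used for names only): 23958 through an accession, 338 through an accession in the cross-reference column, 2496 through a current symbol and 985 through a synonym, while 13223 kept the name in the file. Probe coordinates are those of the files, build hg18 (NCBI36). No genome of that build was used, so exon and UTR positions were not analysed here. A gene with several tested probes was represented by the probe with the highest mean intensity over both arrays and channels. The 12368 named genes tested were counted apart from 5656 tested probes without a gene name. A gene whose probe was not well above background in one channel on both arrays is given as at least N-fold, computed after Aquantile normalization of the channels with the lowest signal among probes well above background as the floor. Such bounds are open to dye bias, since no dye swap balances them.

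The gene lists were fixed before the data were examined: core clock, clock outputs, estrogen receptor targets in both directions, luminal identity, basal and mesenchymal genes, G1/S, G2/M, p53 targets, DNA damage response, apoptosis, type I interferon response, NF-kappa-B and inflammatory cytokines, MHC class I and antigen presentation, unfolded protein and integrated stress response, heat shock and oxidative stress, hypoxia, cholesterol and fatty acid synthesis, TGF-beta targets, Wnt targets, immediate early genes, metallothioneins, ribosomal proteins, mitochondrial respiratory chain, histones, the small RNA pathway, markers of fibroblasts, endothelium and leukocytes, and reference transcripts. Each of the 30 lists was tested with camera (preset inter-gene correlation 0.01), with an estimated correlation and with fry. The genes named were, by a rule set at the same time, CRY2 and the measured core clock genes, the 10 largest rises and 10 largest falls past the threshold with the same sign on both arrays, and up to 4 members per list with the largest change. A further 29 genes, mostly the members of small counts of calls, were named after their values were seen and are marked with a dagger in the report. Unnamed transcripts were skipped in the ranking: 0 among the rises and 10 among the falls.

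Alternatives were no background subtraction, normexp with offset 0, median centring in place of loess, the software's own log ratios, the series table, no filter or a stricter filter on dim probes, flagged spots kept, trended and robust variance models, a separate-channel fit (intraspot correlation 0.27, statmod 1.5.0), a threshold of 0.10, a minimum fold of 1.2 (treat), the software's p-values under 0.01 on both arrays, the mean of a gene's probes, removal of a trend in probe GC content, and each array alone. Removal of the remaining intensity trend over the tested probes was added after the ratios had been seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

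The test was tested on simulated data of 23539 probes on 2 arrays with the measured spread. With 200 planted changes on an otherwise unchanged array, it recovered 0% of log2 changes of 0.50, 86.0% of 1.00, 90.0% of 1.50 and 96.0% of 2.00, and 15 of its 151 calls were false. With an effect on every probe, taken from the measured mean ratios and shrunk, it called 6083, of which 99.1% had the right sign. That count follows from the measured ratios, and no call of an unchanged probe was possible there. With no effect the test called 0 probes, with 4.90% at an unadjusted p under 0.05. The simulated noise was independent between probes and held no dye or GC bias, so these runs do not cover such bias. Of 30 simulated lists, camera called the shifted one and 0 of the 29 others.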

Results

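Gene expression was measured in MCF7 cells, an estrogen receptor-positive human breast cancer line, after transfection with an siRNA against CRY2 or with a negative control siRNA. CRY2 encodes cryptochrome 2, a repressor of the CLOCK-BMAL1 transcription factor in the circadian clock. The comparison asks which transcripts differ after transfection with the siRNA against it. The records carry 1 label, CRY2 siRNA, and compare no different siRNAs against CRY2. In every result below, other effects of the siRNA therefore cannot be told apart from an effect of CRY2 loss. The titles speak of a knockout, while the source labels name siRNAs, so the treatment is described here as a knockdown. There were 2 arrays, each pairing CRY2 siRNA (Cy5) with control siRNA (Cy3) from 1 of 2 independent cell populations. Between 56.3% and 58.3% of the gene spots were well above background per channel and array, and 23539 probes were tested, representing 12368 named genes. Values are log2 ratios of CRY2 siRNA over control siRNA, as mean ± SD with n = 2 arrays throughout, and the number of arrays limits their precision. Genes were named by a rule fixed before the values arrived, and 29 more were named after their values were seen, each marked with a dagger (†). The dyes were not swapped, so no ratio below is free of a possible dye effect.

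The targeted transcript fell. CRY2 had a log2 ratio of -1.64 ± 0.18 (n = 2), with -1.51 and -1.77 on the arrays, which leaves 32.0% of the control level, a 3.13-fold reduction (limma, adjusted p = 0.0200). This value comes from probe A_23_P127394 on chromosome 11, positions 45861256 to 45861315 of build hg18. A second tested CRY2 probe at 45848499 to 45848558 gave -0.15 ± 0.10, and -1.17 and -0.42 in the deposited log ratios. Its red signal was not well above background on either array, so neither these values nor the mean of both probes, -0.90, is a measured ratio. Another CRY2 probe was below the background filter.

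Among the named genes tested, 2990 (24.2%) passed the threshold of limma's moderated test, 1663 higher and 1327 lower with CRY2 siRNA. Of the 5631 probes that passed (3181 higher, 2450 lower), 3800 (67.5%) differed by less than 1.5-fold, and the smallest adjusted p was 0.0194. Large rises outnumbered large falls: 183 of the changed named genes were at least 2-fold higher and 13 at least 2-fold lower. On both arrays at once, 196 probes were at least 2-fold higher, 11 at least 2-fold lower and 13 beyond 2-fold in opposite directions. Across the tested probes, which are not independent replicates, the arrays had Pearson's r = 0.71 and Spearman's rho = 0.74, and 80.1% of probes had the same sign on both. The number of changed probes depends on the processing, from 427 with a required minimum of 1.2-fold to 12621 (10508 higher, 2113 lower) with median centring in place of loess, and the series table gave 1279 higher and 1307 lower. The 207 probes beyond 2-fold in the same direction on both arrays became 1369 with the deposited log ratios and 989 with the series table.

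**Figure D1:**
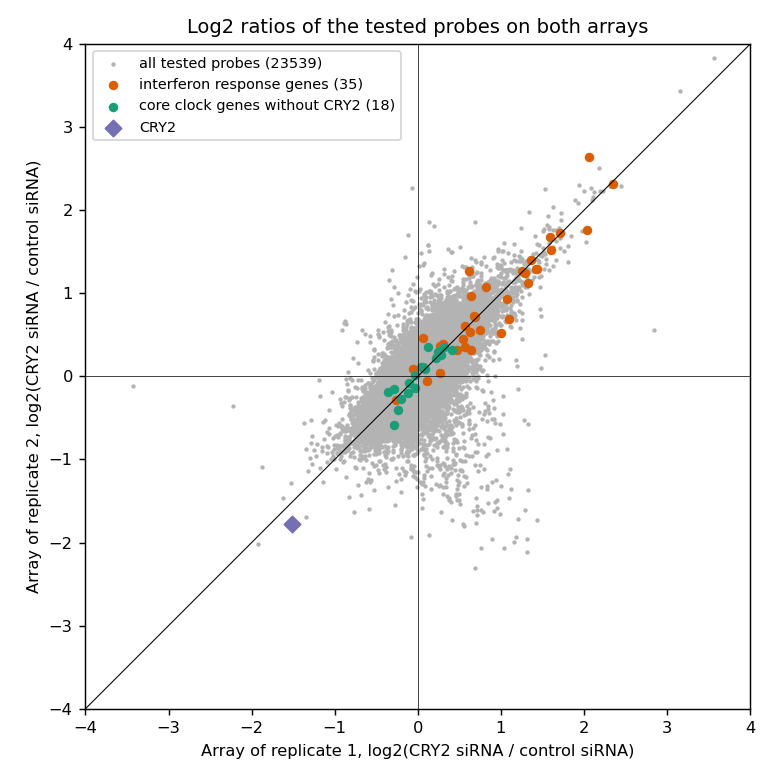
Log2 ratio of CRY2 siRNA over control siRNA on the array of replicate 1 (horizontal axis) against that of replicate 2 (vertical axis), with 1 point per tested probe (grey, 23539 probes). The 35 interferon response genes (orange) lie mostly in the upper right, CRY2 (purple) lies at -1.51 and -1.77, the other 18 core clock genes (green) lie near 0, and the diagonal marks equal values.

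The largest rise was that of KRT6B, a keratin of stratified epithelia, 13.0-fold (log2 ratio 3.70 ± 0.18). The type III interferon genes IFNL2 (3.29 ± 0.19) and IFNL3 (2.23 ± 0.0028) followed, as did the chemokine gene CXCL11 (2.37 ± 0.11), the exonuclease gene ISG20 (2.35 ± 0.41), IFIT2 (2.33 ± 0.020), which acts against viral RNA, and the cytokine gene IL6 (2.30 ± 0.018). IGFBP6, which binds insulin-like growth factors (2.35 ± 0.23), the stress-induced NUPR1 (2.21 ± 0.025) and the aldo-keto reductase gene AKR1B10 (2.17 ± 0.13) completed the 10. All 10 passed limma's test, with adjusted p from 0.0194 to 0.0205. The near-identical copies of IFNL2 and IFNL3, and the close relatives of KRT6B and AKR1B10, can bind the same probes, so these signals are uncertain as to the copy.

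The largest falls in the main values began with CRACR2B, a calcium sensor gene, at -1.97 ± 0.068 (3.92-fold lower), followed by CRY2 and by GRIN1, a glutamate receptor subunit gene, at -1.54 ± 0.12. The other GRIN1 probe had -0.41, not past the threshold (mean of its probes -0.98). The other 7 were NPFFR1 (-1.23 ± 0.13) and KISS1R (-1.14 ± 0.22), both neuropeptide receptor genes, the nuclear lamina gene LMNB1 (-1.14 ± 0.44), CYP4F2 (-1.06 ± 0.26), the potassium channel gene KCNG2 (-1.06 ± 0.044), LONRF2 (-1.05 ± 0.53) and ADAMTSL2. For ADAMTSL2 the red signal was not well above background, so it was at least 1.81-fold lower in the main values, a bound that its ratio did not reach with the GC trend removed or without background subtraction. Adjusted p ranged from 0.0194 to 0.0379 in limma's test. The probes of these 10 genes had a median GC content of 74.2%, against 45.0% for all tested genes. With the GC trend removed, all 10 stayed past the threshold, but NPFFR1 came to -0.77, KISS1R to -0.66, CYP4F2 to -0.68 and KCNG2 to -0.64. With the deposited log ratios NPFFR1 came to -2.65, KCNG2 to -2.31 and ADAMTSL2, at background, to -3.90, beyond CRACR2B (-2.12) and CRY2 (-2.01), so the order of the falls depends on the processing. NPFFR1 and KCNG2 dropped out where both channels had to be well above background, so the size of their falls is uncertain too. LMNB1 and LONRF2 were not past the threshold with the deposited log ratios (adjusted p = 0.0533 and 0.0673).

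Genes of the type I interferon response rose as a group. Of 35 measured, 28 rose and 0 fell (30 and 1 adjusted over the list alone), with a median log2 ratio of 0.76, and 32 were positive on both arrays. Beside ISG20 and IFIT2, the ubiquitin-like modifier ligase gene HERC5 (1.90 ± 0.19) and IFNB1, the interferon beta gene itself (1.71 ± 0.0096), rose. MX1†, an antiviral GTPase gene, had 0.031 ± 0.12 and was not past the threshold. The MHC class I and antigen presentation list had 12 of 17 measured members higher and 0 lower, also 12 and 0 adjusted over the list alone (median 0.67), with HLA-C at 1.86 ± 0.16 and B2M, the class I light chain, at 1.13 ± 0.092. Probes of the HLA genes can bind one another's transcripts. In the NF-kappa-B and cytokine list 11 of 17 rose and 1 fell (12 and 1 adjusted over the list alone; median 0.53), among them IL6, the chemokine gene CCL5 (1.74 ± 0.068) and NFKBIA (0.87 ± 0.060), the inhibitor induced by NF-kappa-B (0.62 and not past the threshold with the deposited log ratios), while the chemokine gene CCL2† fell (-0.58 ± 0.023). CCL2 came to -1.49 with the deposited log ratios and -0.38 without background subtraction, past the threshold in both. It dropped out where both channels had to be well above background. IL18 was at least 1.40-fold higher, its control signal not being well above background. In the NF-kappa-B and cytokine list only 17 of 26 genes were measured. Camera gave adjusted p = 1.05e-13, 3.08e-06 and 4.83e-05 for the 3 lists. Each has adjusted p = 0.584 with an estimated correlation, a test left with 1 residual degree of freedom, in which 0 of the 30 lists passed. Of the leukocyte markers 8 of 20 were measured, with a median of -0.035.

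The core clock list was not past camera's threshold (median -0.0048, adjusted p = 0.998). Of 19 measured members, 3 passed limma's test: CRY2 fell, while NR1D1, which encodes the repressor REV-ERB alpha (0.37 ± 0.070), and TIMELESS (0.33 ± 0.033) rose. CRY2 alone passed adjusted over the list alone. NR1D1 and TIMELESS were not past the threshold with the deposited log ratios (0.42 and 0.37) or with the GC trend removed (0.33 and 0.26). The other members were not past the threshold. CRY1, the paralog of CRY2, had 0.092 ± 0.036, PER1 -0.44 ± 0.21, PER2 -0.16 ± 0.056, PER3 -0.0048 ± 0.038, CLOCK -0.32 ± 0.11, BMAL1 0.27 ± 0.035, NR1D2 0.27 ± 0.011, NPAS2 0.22 ± 0.00022 and RORA 0.24 ± 0.17. The second probes of CLOCK (0.27), CRY1 (-0.095), PER2 (0.17), PER3 (0.23) and CSNK1D (0.20) had the opposite sign, as did, with the control not well above background, those of PER1 (0.096) and RORC (0.38, adjusted p = 0.0469). The brighter RORC probe had -0.24 ± 0.056. CSNK1E had 2 dimmer probes, at -0.046 and 0.096. TIPIN, CSNK1D and CSNK1E, at -0.097, -0.22 and -0.27, turned to rises with median centring. Of 16 measured clock output genes, 4 rose and 1 fell (4 and 1 adjusted over the list alone; median 0.15, camera adjusted p = 0.0225, and 0.584 with an estimated correlation). They were the repressor gene BHLHE40 (1.11 ± 0.11), NOCT (0.79 ± 0.20), NAMPT (0.75 ± 0.090) and the repressor gene NFIL3† (0.44 ± 0.00085), and the peptide hormone gene AVP was lower (-0.96 ± 0.57). AVP lost the threshold with the GC trend removed (-0.54), NFIL3 with the deposited log ratios (0.40), and the list with median centring, the series table, no filter on dim probes and the GC trend removed.

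**Figure D2:**
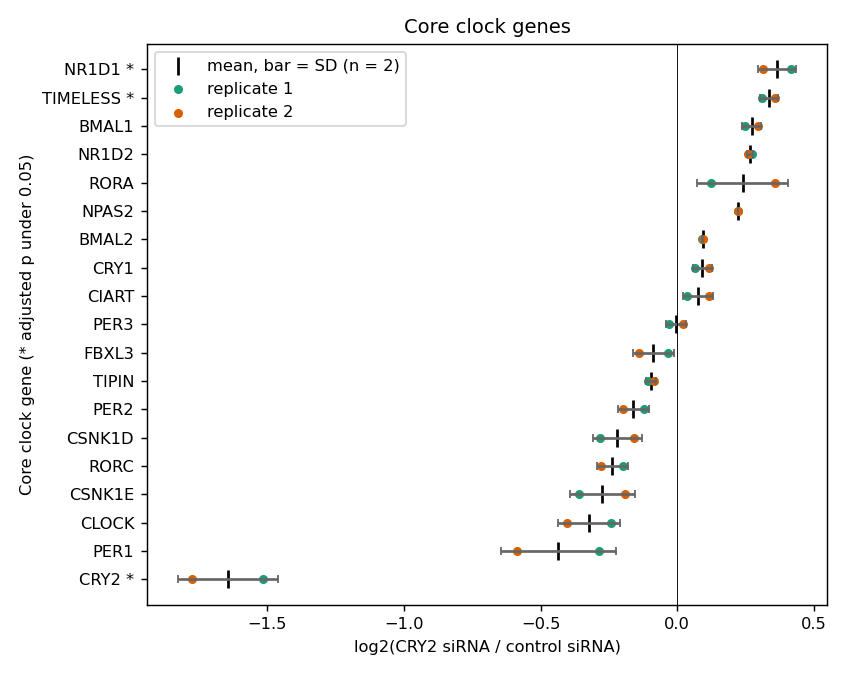
Log2 ratio of CRY2 siRNA over control siRNA (horizontal axis) for the 19 measured core clock genes (vertical axis), with 1 point per array, the mean as a tick and the SD as a bar (n = 2). CRY2 at -1.64 stands apart, and NR1D1 at 0.37 and TIMELESS at 0.33 are the members that rose, marked with an asterisk like CRY2.

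Estrogen receptor targets moved in both directions. Of 27 measured genes that rise with estradiol, 8 rose and 7 fell (9 and 7 adjusted over the list alone; median 0.078, camera adjusted p = 0.381). TFF1, a secreted trefoil peptide gene, rose 4.36-fold (2.12 ± 0.26), the stress transcription factor gene XBP1 had 1.63 ± 0.17 and the growth factor gene AREG 1.08 ± 0.11, whereas the chemokine gene CXCL12† (-1.15 and -0.86 on the arrays), MYB† (-0.94 ± 0.093) and its relative MYBL1 (-1.01 ± 0.42) fell. PIK3IP1† was the estradiol-repressed gene that fell (-0.42 ± 0.10), not past the threshold without background subtraction. MYBL1 was not past the threshold with the deposited log ratios. Of 16 genes that fall with estradiol, 6 rose and 1 fell (7 and 3 adjusted over the list alone; median 0.21, adjusted p = 0.0872), including BCAS1 (0.83 ± 0.040) and EFEMP1 (0.82 ± 0.020). The luminal identity list had 3 of 19 higher and 2 lower (8 and 3 adjusted over the list alone; median 0.23, adjusted p = 0.109), and ESR1†, the estrogen receptor gene, had -0.29 ± 0.10, not past the threshold. Its risen members were KRT19 (1.02 ± 0.15), KRT8 (0.76 ± 0.24) and ERBB3 (0.63 ± 0.27), none of them past the threshold with the deposited log ratios, and CLDN3 fell (-0.67 ± 0.040), to -0.023 with median centring, as did TFAP2C† (-0.39 ± 0.011), to -0.046. In the basal and mesenchymal list 6 of 11 rose and 0 fell (7 and 0 adjusted over the list alone; median 0.31), with the matrix gene FN1 at 1.48 ± 0.034 and the keratin genes KRT17 at 1.40 ± 0.16 and KRT14 at 1.06 ± 0.055, whose other probe had -0.16 (mean of its probes 0.45). Camera gave adjusted p = 0.000472 for the list, and 0.584 with an estimated correlation. Only 11 of its 21 genes were measured, and over the alternatives its median ran from 0.12 to 0.58.

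The G1/S list was lower in the main fit but not with median centring. Of its genes 10 of 29 fell and 1 rose (13 and 1 adjusted over the list alone; median -0.22, camera adjusted p = 0.0205, and 0.584 with an estimated correlation). CDT1, which licenses replication origins, fell to -0.84 ± 0.0030, the nucleotide synthesis genes DHFR to -0.78 ± 0.033 and TYMS to -0.65 ± 0.19, and the helicase gene MCM5 to -0.59 ± 0.11, while CCNE2†, encoding cyclin E2, was higher (0.43 ± 0.19) but lost the threshold under 7 alternatives, among them the GC trend removed (0.36) and the deposited log ratios (0.87). With median centring, where all tested genes had a median of 0.22, the list's median was 0.21 and the call was lost. DHFR was not past the threshold as the mean of its probes (-0.27), nor were TYMS (-0.19) and MCM5 (-0.19) with median centring. The G2/M list had 4 of 29 lower and 1 higher (0 and 0 adjusted over the list alone; median -0.11, adjusted p = 0.166), with BIRC5 at -0.43 ± 0.089, the cyclin gene CCNB2 at -0.40 ± 0.046, ANLN† at -0.40 ± 0.12 and CENPF† at -0.36 ± 0.040, of which BIRC5, CCNB2 and CENPF turned positive with median centring and ANLN came to -0.078 and lost the threshold, and the phosphatase gene CDC25B rose (0.55 ± 0.29), lost with the deposited log ratios. CDC25B kept its call under only 7 of 15 alternatives. Of 25 p53 targets, 4 rose and 1 fell, the same adjusted over the list alone (median 0.093, adjusted p = 0.108), the rises being the stress cytokine gene GDF15 (1.31 ± 0.21), GADD45A (0.87 ± 0.10), the cell cycle inhibitor gene CDKN1A (0.75 ± 0.021) and the death receptor gene FAS† (0.55 ± 0.11). The p53 target BBC3 had 0.68 at its brightest probe and did not pass. Of its 3 probes, at 0.63 to 1.05, 2 were called higher. The DNA damage list had 1 of 29 higher, PPP1R15A (1.25 ± 0.40), and 2 lower, RAD51C (-0.61 ± 0.16) and MSH2† (-0.49 ± 0.17) (1 and 1 adjusted over the list alone; median -0.11, adjusted p = 0.381). RAD51C and MSH2 came to -0.016 and -0.070 with median centring, and PHLDA3†, the fallen p53 target (-0.44 ± 0.097), to -0.072. Among apoptosis regulators 7 of 24 rose and 1 fell (10 and 1 adjusted over the list alone; median 0.15, adjusted p = 0.0140, and 0.584 with an estimated correlation). The rises included the pro-apoptotic PMAIP1 (1.33 ± 0.11) and TNFSF10 (1.30 ± 0.063) and the anti-apoptotic MCL1 (0.66 ± 0.15), and BCL2†, also anti-apoptotic, fell (-0.44 ± 0.16). MCL1 lost the threshold with flagged spots kept and BCL2 with median centring (-0.14). The apoptosis list was not past the threshold with the series table (adjusted p = 0.114).

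Of the stress and signalling lists 6 passed camera with positive medians, and the Wnt and metallothionein lists did not pass. With an estimated correlation the 6 were lost, with adjusted p = 0.654 for the unfolded protein and heat shock lists and 0.584 for the other 4. In the unfolded protein and integrated stress response list 13 of 25 rose and 5 fell (14 and 6 adjusted over the list alone; median 0.36). The transcription factor genes CEBPB (1.42 ± 0.057) and ATF3 (1.30 ± 0.12) rose, whereas the serine and asparagine synthesis genes PHGDH† (-0.89 ± 0.021), PSAT1† (-0.44 ± 0.16) and ASNS† (-0.42 ± 0.054), the glutathione-degrading CHAC1† (-0.59 ± 0.079) and the pseudokinase gene TRIB3† (-0.40 ± 0.14) fell, of which ASNS and TRIB3 turned to 0.18 and 0.30 with median centring and PSAT1 came to -0.12 and lost the threshold. The TGF-beta list had 9 of 19 higher and 0 lower (11 and 0 adjusted over the list alone; median 0.39), with TGFBI at 0.94 ± 0.088. PMEPA1 had 1.70 ± 1.61 and did not pass, while its second probe, at 0.52 ± 0.13, did (adjusted p = 0.0306). Of 24 immediate early and growth factor genes, 12 rose and 0 fell (13 and 1 adjusted over the list alone; median 0.33), among them KLF4 (1.75 ± 0.26), ATF3, PHLDA1 (1.06 ± 0.076) and DUSP5 (1.06 ± 0.0092), while FOS† (-0.13 ± 0.25) was not past the threshold. Hypoxia genes had 6 of 23 higher and 0 lower, the same adjusted over the list alone (median 0.25), with ADM at 1.11 ± 0.11 and NDRG1 at 0.82 ± 0.091. Heat shock and oxidative stress genes had 8 of 21 higher and 1 lower (9 and 1 adjusted over the list alone; median 0.097), with SOD2 at 1.33 ± 0.049 and HSPB1 at 1.08 ± 0.025, while HSP90AA1† was lower (-0.31 ± 0.0025) but rose with median centring (0.42) and was positive, not past the threshold, with the series table (0.11) and as the mean of its probes (0.18). Cholesterol and fatty acid synthesis genes had 6 of 27 higher and 1 lower (9 and 1 adjusted over the list alone; median 0.16), with LDLR at 0.59 ± 0.084, lost as the mean of its probes (0.18), and MVD† lower (-0.49 ± 0.11), lost with median centring (-0.22). Camera's adjusted p for these 6 lists was 0.00754, 0.000521, 4.34e-05, 0.00850, 0.0225 and 0.00754 in this order. The heat shock list was lost with the deposited log ratios, the series table and the GC trend removed. Wnt targets had 3 of 12 higher and 3 lower and metallothioneins 1 of 13 higher and 1 lower, the same adjusted over each list alone, with medians of 0.097 and -3.6e-05, and neither list passed camera (adjusted p = 0.679 and 0.848). The Wnt targets DKK1 (0.60 ± 0.13), MYC (0.50 ± 0.11) and RNF43† (0.34 ± 0.052) rose and ZNRF3 (-0.37 ± 0.11), NKD1 (-0.36 ± 0.064) and WNT11† (at least 1.28-fold in the main values, CRY2 siRNA not well above background) fell, with RNF43, NKD1 and WNT11 not past the threshold with the GC trend removed (0.31, -0.29 and -0.14), MYC at -0.26 in the series table and ZNRF3 at -0.036 with median centring. The ratio of WNT11 did not reach its bound with the GC trend removed or without background subtraction (-0.23). Only 12 of the 18 Wnt targets were measured. The metallothionein genes are near copies of one another, so their probes are uncertain as to the gene. MT2A rose (0.62 ± 0.028) but was not past the threshold with the deposited log ratios (0.51), and MT1A was lower (-0.50 ± 0.075) but at 0.0093 with median centring.

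Abundant housekeeping transcripts were not at a fixed ratio. Of 26 ribosomal protein genes 15 rose and 0 fell (18 and 1 adjusted over the list alone; median 0.40, camera adjusted p = 8.26e-06, and 0.584 with an estimated correlation), for example RPL7A (0.93 ± 0.12) and RPS19 (0.91 ± 0.075). These genes have processed pseudogenes, so their signals are uncertain as to the copy. The list lost its call with the series table (median 0.10, adjusted p = 0.148), as did both genes (0.30 and 0.41), and random lists of genes as bright had a median of 0.29. The reference transcripts had 4 of 14 higher and 1 lower, the same adjusted over the list alone (median 0.16, adjusted p = 0.108): ACTB (1.43 ± 0.21), UBC (1.24 ± 0.38), B2M and GUSB (0.50 ± 0.066) rose and HMBS†, a heme synthesis gene, was lower (-0.50 ± 0.011), while GAPDH† had -0.38 ± 0.22 and did not pass, and both turned positive with median centring (0.16 and 0.30). ACTB was not past the threshold with the series table (0.52), nor UBC and GUSB with the deposited log ratios. The mitochondrial list had 1 of 24 higher and 2 lower (0 and 0 adjusted over the list alone; median -0.15, adjusted p = 0.381), but rose with median centring (0.47). Its fallen members NDUFS3 (-0.43 ± 0.091) and COX7A2 (-0.36 ± 0.071) turned positive there (0.13 and 0.31), and ATP5F1C† was higher (0.33 ± 0.032), not past the threshold with the GC trend removed (0.26). Histone genes had 1 of 16 higher and 3 lower (1 and 4 adjusted over the list alone; median -0.13, adjusted p = 0.476), with H3-3B at 1.07 ± 0.29 and H2AC25 at -0.72 ± 0.072 (-0.17 and not past the threshold with median centring), while H1-2 and H2BC5†, lower at -0.53 ± 0.14 and -0.35 ± 0.094, had 0.047 and 0.049 with median centring. H3-3B was not past the threshold with the series table (0.42), and histone probes are uncertain as to the copy. The small RNA pathway had 0 of 15 higher and 2 lower (0 and 4 adjusted over the list alone; median -0.042, adjusted p = 0.679), TARBP2 (-0.38 ± 0.053), at -0.027 with median centring, and GEMIN4 (-0.38 ± 0.13), the second of which turned to 0.046 with median centring. Markers of fibroblasts (1 of 6 higher and 1 lower, 2 and 2 adjusted over the list alone), endothelium (1 of 5 higher and 1 lower, the same adjusted over the list alone) and leukocytes (1 of 8 higher and 0 lower, the same adjusted over the list alone) had medians of -0.085, -0.15 and -0.035 and did not pass camera (adjusted p = 0.804, 0.679 and 0.679). Only 6 of 14 fibroblast markers and 5 of 12 endothelial markers were measured. The called fibroblast genes were FAP (0.47 ± 0.027), higher, and THY1 (-0.70 ± 0.078), lower. The risen leukocyte marker was CD68 (0.98 ± 0.016), a lysosomal gene. With the deposited log ratios FAP came to 1.09 and CD68 to 2.01. Both called endothelial genes had limits: ROBO4 was at least 1.29-fold lower in the main values and not past the threshold with the GC trend removed, and CLDN5 had one probe at 1.26 and another at -0.63.

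**Figure D3:**
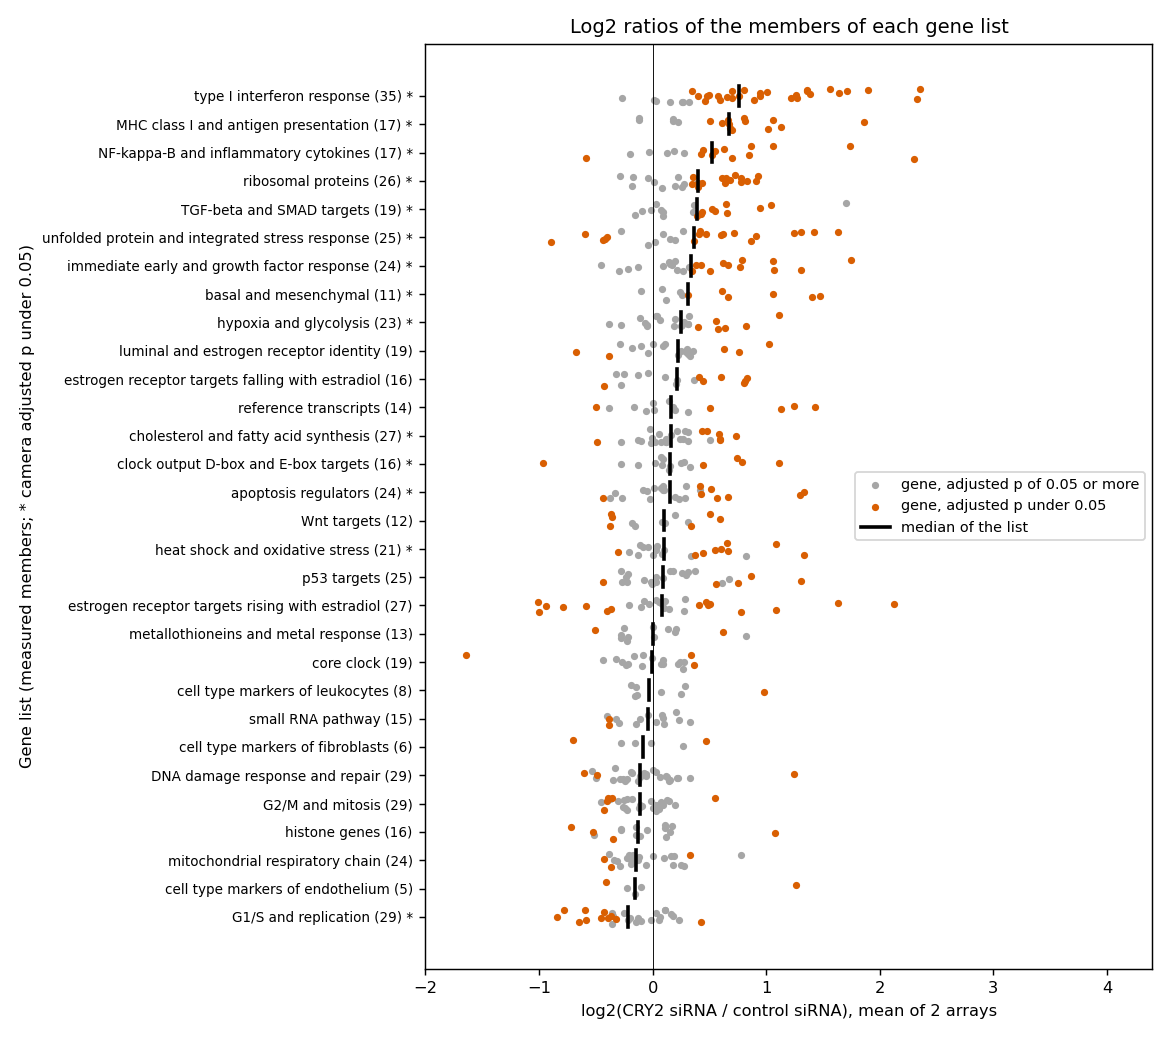
Log2 ratio of CRY2 siRNA over control siRNA, mean of 2 arrays (horizontal axis), for each measured member of the 30 gene lists (vertical axis, with the number of measured members), orange where limma's adjusted p was under 0.05. The black bar is the list's median, from -0.22 for G1/S genes (0.21 with median centring) to 0.76 for interferon genes, and the 14 lists past camera's threshold carry an asterisk (0 with an estimated correlation).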

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

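The fall of CRY2 kept its direction and its side of the threshold under all 15 alternatives that tested single genes. The fall ran from -2.01 to -0.90 (the mean with a probe at background) against -1.64 in the main fit, with adjusted p from 0.00176 to 0.0298 in limma's test. Of the 111 called genes that the rule named, 62 stayed past the threshold under every such alternative, 49 did not under at least 1, and 103 kept their sign throughout. Of the 25 called genes named after their values were seen, 6 stayed past it and 19 kept their sign. The required minimum of 1.2-fold and the software's p-values were applied to counts only, so single genes and lists were not followed under them. The removal of a residual intensity trend was chosen after seeing the data, and all other alternatives were planned. Signal over background limits rises and falls: between 56.3% and 58.3% of the gene spots were well above it per channel, and among tested probes 836 had the control and 537 the CRY2 siRNA channel not well above it on both arrays, so the size of their fitted ratios is uncertain. The bounds given as at least N-fold hold for the main values. The main fit was already paired, because the groups meet on each array as a ratio, so no separate paired analysis was run. Where a reason is not given below, the cause was not tested.

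The counts, against 5631 probes (3181 higher, 2450 lower) and 2990 genes (1663 higher, 1327 lower), moved as follows. With a required minimum of 1.2-fold there were 427 probes (371 higher, 56 lower) and 264 genes (242 higher, 22 lower), fewer by construction, and with Agilent's p on both arrays 2962 probes (1771 higher, 1191 lower) and 1444 genes (861 higher, 583 lower), of whose probes limma called 2926. Median centring gave 12621 probes (10508 higher, 2113 lower) and 7148 genes (6180 higher), so that 83.3% of called probes were higher against 56.5% in the main fit. The deposited log ratios gave 3275 probes (1775 higher, 1500 lower) and 1563 genes (850 higher, 713 lower), and the values of the series table gave 2586 probes (1279 higher, 1307 lower) and 1514 genes (830 higher, 684 lower). Without the filter on dim probes there were 10197 probes (5460 higher, 4737 lower) and 4752 genes (2349 lower), with more probes tested, and with the threshold at 0.10 there were 9835 probes (5115 higher, 4720 lower) and 5212 genes (2650 higher, 2562 lower). The number lower was 1590 probes and 875 genes without background subtraction, 1458 and 769 with the GC trend removed, and 2006 genes with separate channels.

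The arrays' r of 0.71 became 0.73 without background subtraction, 0.80 with median centring, 0.69 with the deposited log ratios, 0.66 with the series table, 0.73 with both channels above background and 0.70 with the GC trend removed. Beyond 2-fold in the same direction on both arrays lay 207 probes, 754 with median centring, 1369 with the deposited log ratios, 989 with the series table, and 1242 at 1.5-fold. The span of the 10 spike-ins was 0.64 log2 units, 0.42 without background subtraction, 0.54 with median centring and 3.01 with the deposited log ratios.

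List results are given as the median and the adjusted p. With an estimated correlation, which leaves 1 residual degree of freedom, all 14 calls were lost: adjusted p = 0.584 for clock outputs (0.15), basal (0.31), G1/S (-0.22), apoptosis (0.15), interferon (0.76), NF-kappa-B (0.53), MHC class I (0.67), hypoxia (0.25), cholesterol (0.16), TGF-beta (0.39), immediate early (0.33) and ribosomal (0.40), and 0.654 for unfolded protein (0.36) and heat shock (0.097). With fry the calls lost were clock outputs (0.15, 0.153), basal (0.31, 0.0738), G1/S (-0.22, 0.101), apoptosis (0.15, 0.101), interferon (0.76, 0.0546), MHC class I (0.67, 0.0689), unfolded protein (0.36, 0.137), heat shock (0.097, 0.133), hypoxia (0.25, 0.102), cholesterol (0.16, 0.0606), TGF-beta (0.39, 0.119), immediate early (0.33, 0.0738) and ribosomal (0.40, 0.0546), and those gained estradiol-induced (0.078, 0.0418), estradiol-repressed (0.21, 0.0426) and luminal (0.23, 0.0426). With fry's test of mixed directions the calls lost were cholesterol (0.16, 0.0746) and TGF-beta (0.39, 0.0502), and those gained estradiol-induced (0.078, 0.0327), estradiol-repressed (0.21, 0.0156), luminal (0.23, 0.0477), p53 (0.093, 0.0198), histone (-0.13, 0.0327), small RNA (-0.042, 0.0354), fibroblast (-0.085, 0.0477), leukocyte (-0.035, 0.0151) and reference (0.16, 0.0327).

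Median centring turned the G1/S list to 0.21 and the mitochondrial list to 0.47, ended the call of clock outputs (0.42, 0.225) and added luminal (0.65, 0.00998), p53 (0.44, 0.0156), endothelial (-0.21, 0.0492) and reference (0.69, 0.00629). The deposited log ratios ended heat shock (0.11, 0.0953), the series table clock outputs (0.15, 0.0912), apoptosis (0.063, 0.114), heat shock (0.11, 0.0733) and ribosomal (0.10, 0.148), and no filter on dim probes clock outputs (0.094, 0.0537). The GC trend removed ended clock outputs (0.078, 0.0697) and heat shock (0.023, 0.0697) and added G2/M (-0.15, 0.0224). The mean of a gene's probes added estradiol-repressed (0.29, 0.0429) and p53 (0.19, 0.0311), separate channels estradiol-repressed (0.21, 0.0125) and reference (0.16, 0.0414), and a threshold of 0.10 estradiol-repressed (0.21, 0.0872). No other alternative changed a list call.

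The genes that turned sign with median centring were TIPIN 0.34, CSNK1D 0.35, CSNK1E 0.36, BIRC5 0.10, CCNB2 0.19, MT1A 0.0093, MT1G 0.28, NDUFS3 0.13, COX7A2 0.31, H1-2 0.047, GEMIN4 0.046, CENPF 0.14, ASNS 0.18, TRIB3 0.30, HSP90AA1 0.42, H2BC5 0.049, HMBS 0.16 and GAPDH 0.30. That setting moved the median of all tested genes from -0.028 to 0.22, and turned values under 0.22 lay below that median, while the turned genes moved by more than it did. Loess subtracts a curve in intensity and median centring a constant of each array, so the shift of a spot between them depends on its array and intensity. Which setting lies nearer to the true ratios was not tested. With the series table MYC -0.26 and HSP90AA1 0.11 turned, and with the mean of a gene's probes HSP90AA1 0.18. The following counts cover only the 146 genes named by the rule and the 29 named after their values were seen. Of these, 54 kept their sign but lost the threshold with the deposited log ratios, 56 with the series table, 21 with the GC trend removed and 7 with the intensity trend removed.

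Called genes that kept their sign but lost the threshold were, with the deposited log ratios, LMNB1, LONRF2, NR1D1, TIMELESS, AVP, MYBL1, SMAD3, KRT19, KRT8, ERBB3, TYMS, MCM5, CDC25B, BIRC5, CCNB2, RAD51C, MCL1, CASP7, NFKBIA, HSPD1, PFKFB3, MSMO1, TGFB2, MYC, ZNRF3, NKD1, MT2A, MT1A, RPLP0, RPL13, NDUFS3, COX7A2, H3-3B, H1-2, GEMIN4, TARBP2, UBC, GUSB, NFIL3, TFAP2C, CCNE2, ANLN, CENPF, PHLDA3, MSH2, BCL2, PSAT1, ASNS, TRIB3, HSP90AA1, RNF43, ATP5F1C, H2BC5 and HMBS. With the series table, LMNB1, LONRF2, NR1D1, TIMELESS, AVP, MYBL1, SMAD3, KRT19, KRT8, CLDN3, ERBB3, DHFR, TYMS, CDC25B, BIRC5, CCNB2, PPP1R15A, RAD51C, CASP7, HSPD1, PFKFB3, MSMO1, SCD, LDLR, TGFB2, ZNRF3, NKD1, MT2A, MT1A, RPL7A, RPS19, RPLP0, RPL13, NDUFS3, COX7A2, H3-3B, H1-2, GEMIN4, TARBP2, CLDN5, ACTB, GUSB, NFIL3, TFAP2C, CCNE2, ANLN, PHLDA3, MSH2, BCL2, PSAT1, ASNS, TRIB3, RNF43, ATP5F1C, H2BC5 and HMBS. With no background subtraction, LONRF2, AVP, CDC25B, HSPD1, ZNRF3, NKD1, GEMIN4, ROBO4, PIK3IP1, CCNE2, ANLN, BCL2, PSAT1, TRIB3, HSP90AA1, WNT11 and H2BC5. With the mean of a gene's probes, NR1D1, AVP, DHFR, CDC25B, HSPD1, PFKFB3, SCD, LDLR, MYC, ZNRF3, RPL13, CLDN5, CCNE2, TRIB3 and H2BC5. With the GC trend removed, NR1D1, TIMELESS, AVP, CLDN3, ERBB3, CDC25B, HSPD1, TGFB2, NKD1, MT1A, H1-2, GEMIN4, TARBP2, ROBO4, CCNE2, PHLDA3, MVD, WNT11, RNF43, ATP5F1C and H2BC5. With a robust variance model, AVP and CDC25B. With the residual intensity trend removed, AVP, CDC25B, HSPD1, GEMIN4, CCNE2, CENPF and H2BC5. With median centring, CLDN3, TYMS, MCM5, RAD51C, ZNRF3, H2AC25, TARBP2, TFAP2C, ANLN, PHLDA3, MSH2, BCL2, PSAT1 and MVD. With separate channels, CDC25B, CCNE2 and MVD. With flagged spots kept, MCL1. With both channels required above background, HSP90AA1. With a trended variance model, HSP90AA1 and RNF43.

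On single arrays, which allow no test, the probes beyond 2-fold numbered 326 to 566 and CRY2 had -1.77 to -1.51. The list medians were estradiol-induced 0.050 to 0.085, luminal 0.19 to 0.22, basal 0.32 to 0.40, G2/M -0.095 to -0.085, DNA damage -0.10 to -0.092, apoptosis 0.19 to 0.19, interferon 0.69 to 0.71, MHC class I 0.62 to 0.68, unfolded protein 0.31 to 0.35, heat shock 0.13 to 0.17, hypoxia 0.17 to 0.25, TGF-beta 0.39 to 0.45, Wnt 0.041 to 0.046, immediate early 0.34 to 0.38, ribosomal 0.37 to 0.38, mitochondrial -0.17 to -0.095, endothelial -0.18 to -0.17 and reference 0.13 to 0.14. For the other lists they were core clock -0.031 to 0.022, clock outputs 0.12 to 0.18, estradiol-repressed 0.20 to 0.23, G1/S -0.23 to -0.20, p53 0.064 to 0.11, NF-kappa-B 0.51 to 0.54, cholesterol 0.12 to 0.23, metallothionein -0.13 to 0.13, histone -0.19 to 0.017, small RNA -0.090 to -0.012, fibroblast -0.088 to -0.082 and leukocyte -0.046 to -0.021. The core clock, metallothionein and histone medians had opposite signs on the arrays. No called list changed sign on a single array.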

Other observations

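The families and genes in this paragraph were chosen after their values were seen. The interferon genes themselves rose, not only their targets: of 8 measured, 7 were higher and 0 lower (median 1.41), among them IFNL1 (1.64 ± 0.18), which like IFNL2 and IFNL3 encodes a type III interferon, IFNA4 (1.18 ± 0.15) and IFNA14 (at least 1.10-fold higher, its control signal not being well above background). The alpha genes are near copies, so their probes are uncertain as to the gene. Of 6 guanylate-binding proteins, GTPases that act against intracellular pathogens, 4 rose and 0 fell (median 0.90), with GBP5 at 1.74 ± 0.0034 and GBP1 at 1.53 ± 0.034. IDO1, which degrades tryptophan, rose at least 3.88-fold, and the chemokine gene CCL3 at least 1.71-fold, both with the control not well above background. Of 11 CC chemokines 5 rose and 2 fell (median -0.037) and of 7 CXC chemokines 4 rose and 1 fell (median 0.49), of whose 5 calls 2 were lost with the GC trend removed, CXCL9 (1.10 ± 0.54) among them. CCL4 (1.14 ± 0.089) and CX3CL1 (1.75 ± 0.0066), which recruit lymphocytes and monocytes, rose, while CCL13 was at least 1.25-fold lower, its CRY2 siRNA signal not being well above background. With median centring, the deposited log ratios and the GC trend removed, every called interferon and guanylate-binding protein gene kept its sign and the threshold.

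The keratins and aldo-keto reductases, also chosen after their values were seen, had members of both directions. Of 28 keratins 13 rose and 3 fell (median 0.21). Beside KRT6B, the epithelial keratins KRT80 (1.33 ± 0.17) and KRT6A (1.04 ± 0.0052) and the hair keratin KRT81 (1.10 ± 0.11) rose, as did KRT23 (at least 4.28-fold) and KRT6C (at least 1.56-fold), whose control signals were not well above background, and probes of KRT6A and KRT6C are uncertain as to the copy. The keratin genes KRT85 (-0.50 ± 0.011), KRT15 (-0.47 ± 0.23) and KRT33A (-0.41 ± 0.00082) fell. Of 16 called keratins, 5 lost the threshold with the deposited log ratios. Of 10 aldo-keto reductases, which reduce carbonyls, 5 rose and 1 fell (median 0.12), with AKR1B1 at 2.01 ± 0.16, AKR1C1 at 1.03 ± 0.22 and AKR1C3 at 0.60 ± 0.11. The fallen AKR7L turned sign with median centring. On the arrays, 250 probes lay more than 1 log2 unit higher in replicate 1 than in replicate 2 (medians 0.48 and -1.04), 82.8% of them unnamed against 24.0% of all tested probes, and 49 lay the other way. Of the spike-ins, E1A_r60_a22 had -0.27 and 0.16 on the arrays.

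Of the tests that follow, those of leukocyte RNA and of the siRNA duplex and the breakdown of calls lost with the GC trend removed were chosen after the result was seen, and the test of second probes with the GC trend removed after the count of 3769 was seen but before its own result. The rise of the interferon list was weighed against dye bias of single probes, which second, non-overlapping probes argue against: 16 such probes had a median of 0.45, at the 99.99th percentile of random draws, and 9 were called higher. Leukocyte markers as a set showed no rise of that size. Their median was -0.035 (8 of 20 measured) against a bound of 0.38 taken from the list's median, though CD68 among them rose (0.98). Measured markers can have a signal from the MCF7 cells themselves, so a small admixture of leukocyte RNA need not move them and stays open. A response to the siRNA duplex, with IFNB1 at 1.71, cannot be told apart from an effect of CRY2 loss, because the records carry 1 label, CRY2 siRNA, and compare no different siRNAs against CRY2. No biological explanation was tested.

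The call of 23.9% of the probes was weighed against dye bias of single probes and against probe GC content. Across 4096 genes with a second, non-overlapping probe, representative and second probe had r = 0.49. Of 62 genes named by the rule with several tested probes, 19 had probes of both signs. Second probes had the sign of the representative for 83.2% of 352 genes changed by at least 1.5-fold (62.0% by chance). For genes changed by less it was 75.8% of 608 (50.6% by chance). Both shares argue against bias of single probes as the whole cause. With the GC trend removed from both probes these shares were 83.2% (61.8% by chance) and 76.0% (50.6% by chance), which argues against GC content as the whole cause, while the count did not settle it: 3769 of 5631 probes still passed, short of the bound set beforehand for excluding it, and 1458 in place of 2450 were lower. Of the changes under 1.5-fold 48.0% still passed, and the 1976 that did not had a median absolute log2 ratio of 0.40 before and 0.30 after with a median SD of 0.064 and 0.065, so their ratios shrank, and the largest unadjusted p that passed also fell, from 0.0120 to 0.00800. Of the larger changes 89.2% still passed, and the 197 that did not went from 0.65 to 0.52 with a median SD of 0.26 and 0.25. A dye effect shared by all probes of a transcript stays open, as the dyes were not swapped.

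The rise of the ribosomal protein list was weighed against scaling of the channels by intensity and against dye bias of single probes, and neither was excluded. Random lists of genes as bright had a 99th percentile of 0.60 and a median of 0.29, and the list, at 0.40, lay at their 81.8th percentile. Second probes of the list's genes had a median of 0.11 (14 probes, 2 called higher), where the representatives of those genes had 0.50. With the residual intensity trend removed, a setting chosen after the data were seen, the list kept its call. Whether the rise is one of bright probes or of ribosomal protein genes was not settled.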
